A study of Mus musculus with 12 samples.

How the data were processed

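RNA from epididymal white adipose tissue (eWAT, the visceral fat pad attached to the epididymis) of C57BL/6 mice was sequenced in 12 libraries. The mice were wild type (WT) or carried the genotype labelled TET KO (TKO), which the series title describes as ablation of TET proteins in adipocytes, and were fed a normal diet (ND) or a high-fat diet (HFD). TET proteins are enzymes that oxidise 5-methylcytosine in DNA and start its removal. The 4 groups, ND_WT, ND_TKO, HFD_WT and HFD_TKO, held 3 biological replicates each, per the labels' protocols. Total RNA was extracted with a column kit and libraries followed standard Illumina protocols, per the labels' protocols. Each library was assigned to its group from its title, and each column of the table was matched to its library by the name that the labels give.

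The deposited table held one value per gene and library in CPM (read counts scaled to a common library total), per the file headers, which name the columns raw CPM. STAR 2.7.3a, featureCounts 2.0.0, DESeq2 and the build mm10 are named per the submitters' processing notes, without a statement of which tool made the CPM table. The annotation release, the use of strand in counting and the treatment of multi-mapped reads were not given in the sources used here. Values of overlapping and antisense genes are therefore uncertain. The table listed 25232 genes, of which 3 had no symbol. Those 3 held between 0.0313% and 0.0679% of each library's CPM and were left out of all tests. A set of 89 tested genes had values identical to another gene in every library, so their reads could not be assigned to a single gene. The 13 mitochondrially encoded genes of a list fixed beforehand were not analysed here.

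The unit was examined before any test was chosen. In each library the deposited CPM values were whole multiples of a constant step after an offset of 0.01 read was subtracted. With a tolerance of 0.05 read, 100% of values in every library came out as whole reads. Recovered totals lay between 20973140 reads (ND_WT replicate 1) and 25606629 reads (HFD_WT replicate 1). A count of 0 at these depths allows up to 3 reads, which corresponded to between 0.117 and 0.143 CPM per library and covers counting error only. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom between 6.20 and 71.5), so no library was counted as a duplicate of another.

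The test plan written before the data were examined assumed raw counts and edgeR, with limma as the test for normalised values. As the deposited unit was CPM, the main test was limma 3.58.1 with a mean-variance trend on log2(CPM + 1), in R 4.3.3. Fold changes are on that scale, which understates the change of low genes. All 12 libraries entered 1 fit with a mean per group and no other covariate, leaving 8 residual degrees of freedom. Genes with a CPM of at least 0.5 in at least 3 libraries were tested (15597 genes); this filter was not part of the plan and was set once the unit was known. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. All adjusted p-values of genes are from limma unless another tool is named. Contrasts were TKO against WT on each diet, HFD against ND in each genotype, and the genotype by diet interaction, which is the TKO effect on HFD minus the TKO effect on ND.

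CPM scales each library to its total over the listed genes. A few abundant genes can move all others under such scaling: the 10 most abundant genes held between 6.99% and 17.1% of reads per library. Trimmed mean (TMM) scaling factors of the recovered reads lay between 0.914 and 1.12. Relative to CPM, TMM scaling shifted the median log2 change of all genes by 0.06 (TKO on ND), 0.14 (TKO on HFD), -0.16 (HFD in WT), -0.08 (HFD in TKO) and 0.08 (interaction). The median change of all genes on the CPM scale was -0.06, -0.10, 0.13, 0.07 and -0.06 in the same order. The total higher and lower genes of each contrast are given with both scalings for this reason, and list members with TMM scaling where the larger of both counts moved by more than 1.5 times or the camera call changed.

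A total of 30 gene lists were fixed before the data were examined, covering adipocyte pathways and markers of other cell types that a fat pad can hold, and 29 of them had tested genes. Lists were compared with all other genes by camera in limma with a preset correlation between genes of 0.01, adjusted over the lists within a contrast. Camera was repeated with a correlation estimated from the data, under which no list was called in any contrast. The fry test was run as a self-contained test, which asks whether a list's genes move, on balance, one way (or in either direction) and does not compare the list with other genes. Member counts refer to calls over all tested genes, and counts "adjusted over the list alone" are given beside them.

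Genes were named by a rule fixed before the data were examined. The rule held a panel of 30 genes in any comparison, the 8 genes per direction and contrast with the largest fold change among called genes whose groups did not overlap and whose mean was at least 1 CPM in the higher group (gene models with Gm or Rik names left out), and up to 4 members per list and contrast with the smallest p-value. The text names a subset of these, and the results of 2 genes are not reported here. Kcnj15, Adtrp and Ucp3 on HFD, Cd163, Lyve1, Mgl2 and Retnla outside the interaction, and the neighbours of Cidea were chosen after their values were seen. Ucp1 and Il6 of the panel stayed below the filter. Coordinates are from the RefSeq annotation of GRCm38.p6, the assembly behind mm10, in which 99.1% of tested genes were found by symbol.

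The steps were tested on simulated reads drawn from the real means, library sizes and spreads, with a known set of changed genes. Each run changed 208 to 220 genes, fewer than any real comparison called. All groups started from the means of the reference group, and genes were drawn independently of each other. The shares below therefore need not hold for the real comparisons. With the macrophage list planted at a doubling, limma recovered 71.3% of 2-fold and 87.8% of 4-fold changes in the simulated TKO comparison on ND (15252 genes run), 69.7% and 90.9% on HFD (15440 genes), 80.5% and 96.0% for HFD in WT (15269 genes), and 71.7% and 88.4% for HFD in TKO (15156 genes). Unchanged genes made up 4.00%, 6.49%, 1.55% and 5.17% of its calls in that order, and 3.45%, 5.82%, 2.07% and 5.17% of the calls of edgeR with TMM factors. The first planting tried was the mature adipocyte list, which holds a large share of the reads. With that list doubled, unchanged genes made up 31.9%, 5.95%, 19.1% and 19.9% of the limma calls on CPM, against 3.37%, 5.73%, 2.03% and 5.06% for edgeR with TMM factors. Calls of small shifts on the CPM scale can thus be a product of scaling when abundant adipocyte genes change, and the totals are printed with both scalings for that reason.

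Alternatives fixed beforehand were another pseudocount (0.1 and 5), no filter, a filter at 1 CPM, edgeR 4.0.16 with RLE factors, DESeq2 1.42.0 and limma-voom on recovered reads, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each replicate in turn. Added after seeing the data were edgeR with TMM factors on recovered reads, TMM-scaled CPM, leaving out each library in the list tests, and the alternatives for genes called under both diets. The edgeR quasi-likelihood test with TMM factors, run on reads of which 100% of values were whole, called 848, 7346, 8889, 2873 and 4332 genes in the order of contrasts above. Overlap between contrasts that share libraries was set beside 100 simulations of unchanged groups. No sequencing batch was given in the labels. The labels do not say that a replicate number is shared by animals, litters or days. Deviations from the group means of libraries with the same number correlated over 0.1 in all 3 pairs between ND_TKO and HFD_TKO (0.39, 0.56 and 0.12) and in all 3 pairs of no other 2 groups. In each combination of 2 groups at least 1 of the 6 possible pairings had all correlations over 0.1. For HFD in TKO a block of replicate number among the TKO libraries was therefore run as an alternative, added after seeing the data.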

Results

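Transcript levels were measured by RNA sequencing in eWAT of 12 mice, 3 in each of the groups ND_WT, ND_TKO, HFD_WT and HFD_TKO. The tissue was sequenced whole, so each value averages adipocytes with the macrophages, lymphocytes, vessels, stroma and mesothelium of the fat pad. Recovered totals lay between 20973140 and 25606629 reads per library. Group values are given as the mean ± SD of CPM (n = 3 mice), and changes as log2 differences with their standard error (SE) on the log2(CPM + 1) scale. The stated purpose of the series was to find transcriptional changes of adipocytes between WT and TET KO mice.

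Tet1, Tet2 and Tet3, the genes of the TET enzymes, were examined first. Tet1 (chromosome 10 of mm10, 62804570 to 62887469) was low in all groups, with 1.48, 0.415 and 0.822 CPM in the ND_WT libraries, 2.77, 2.22 and 2.98 in ND_TKO, 0.86, 0.841 and 0.996 in HFD_WT, and 3.07, 2.07 and 1.65 in HFD_TKO. Tet2 (chromosome 3, 133463677 to 133545136) stood at 23.6, 18.4 and 14.7 CPM in ND_WT, 15.1, 23.5 and 15.7 in ND_TKO, 13.7, 16.2 and 17.8 in HFD_WT, and 9.54, 13.4 and 10.7 in HFD_TKO. Tet3 (chromosome 6, 83362373 to 83457208) stood at 42.0, 35.5 and 39.7 CPM in ND_WT, 48.5, 49.1 and 40.0 in ND_TKO, 64.6, 70.5 and 71.7 in HFD_WT, and 61.0, 62.4 and 58.9 in HFD_TKO. None of the 3 genes was lower in the libraries labelled TKO by the main test. Tet1 was higher in TKO on ND (log2 change 0.97, SE 0.21, adjusted p = 0.019) and on HFD (0.76, SE 0.21, adjusted p = 0.010). On ND that call ended without ND_WT replicate 2 (adjusted p = 0.064), ND_TKO replicate 1 (0.062) or ND_TKO replicate 3 (0.076), and when only these groups were fitted (0.072). Tet2 differed by -0.47 on HFD (adjusted p = 0.066), and the call was made without HFD_TKO replicate 2 (-0.60, adjusted p = 0.042) and when only these groups were fitted (adjusted p = 0.028). Reads over a whole gene include exons left after a deletion and cells other than adipocytes, and the deleted exons were not given in the labels, so these values do not check the labels. TKO stands here for the libraries labelled so.

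In a principal component analysis the first component held 64.3% of the variance, and the HFD_WT libraries lay at 72.6 to 72.9 on it. The HFD_TKO libraries lay at -8.09 to 0.462, between these and the ND libraries of both genotypes at -44.0 to -25.7. On the second component, with 15.8% of the variance, the HFD_TKO libraries lay at 18.5 to 44.2 (replicate 1 at 44.2), and all other libraries at -32.6 to 13.7. There ND_WT replicate 3 lay at -6.21, apart from ND_WT replicates 1 and 2 at -32.0 and -32.6 and beside ND_TKO replicate 2 at -7.28. That library correlated with ND_TKO replicates 1, 2 and 3 at 0.988, 0.980 and 0.986, and with ND_WT replicates 1 and 2 at 0.983 and 0.982. Leptin (Lep), a hormone of enlarged adipocytes, stood at 2588 CPM in ND_WT replicate 3 against 689 and 495 CPM in replicates 1 and 2.

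**Figure D1:**
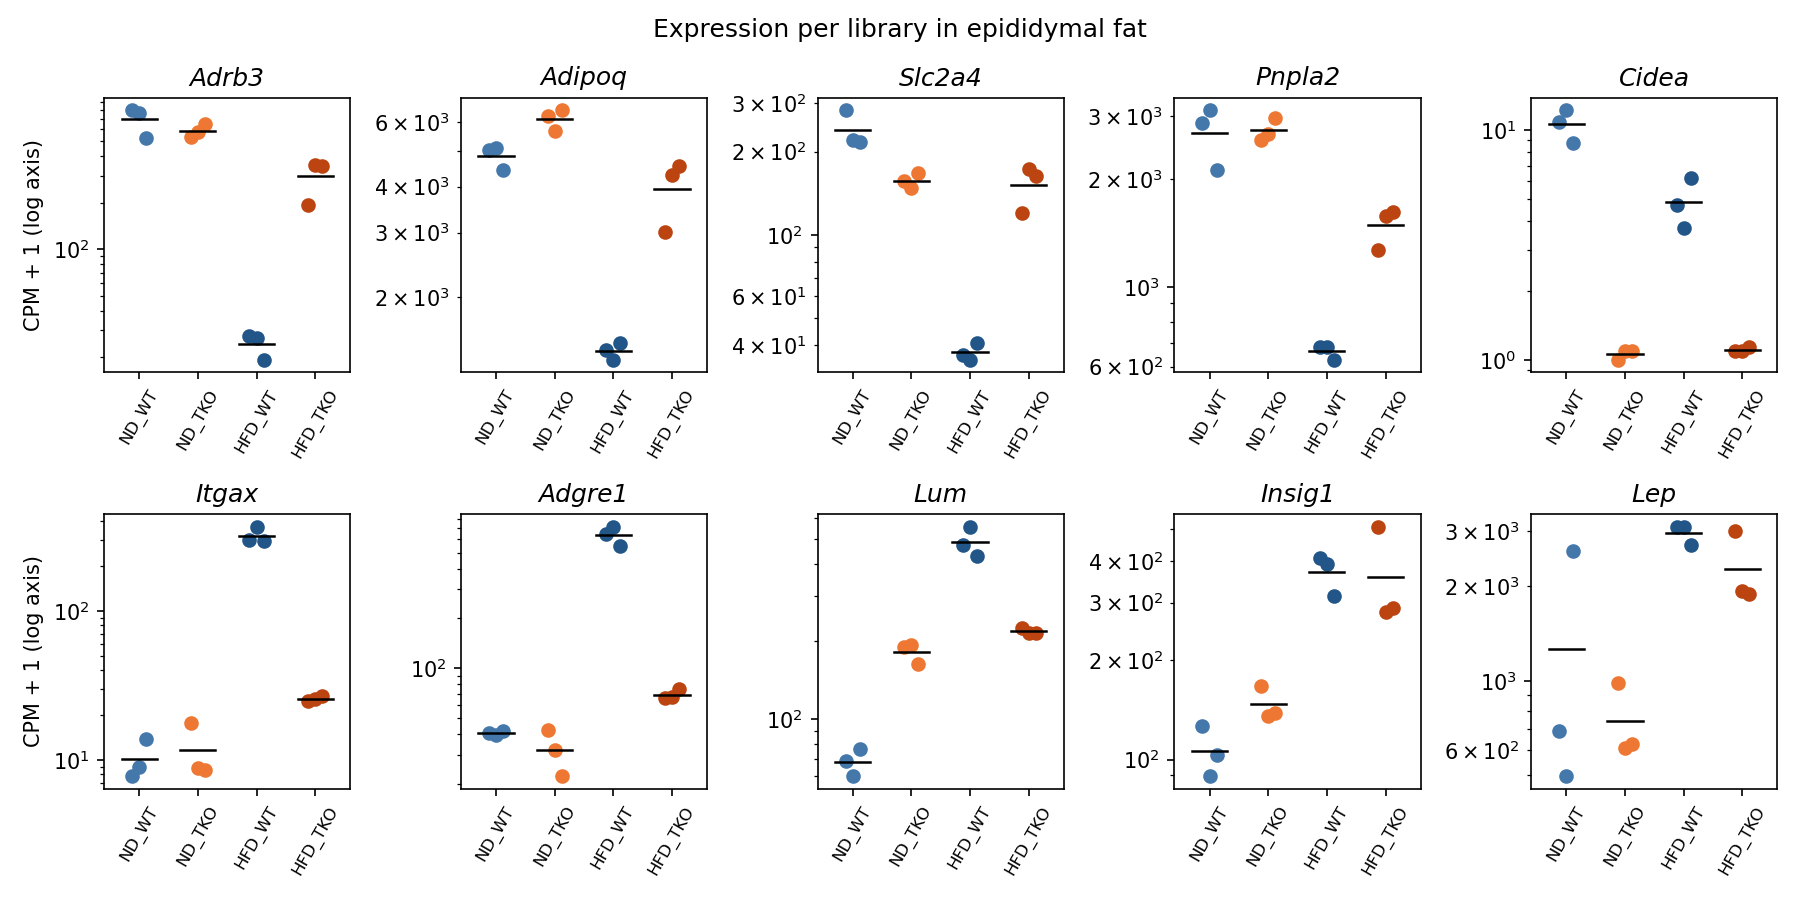
Levels of 10 genes as CPM + 1 on a log axis in the 4 groups, with 1 dot per library and a line at the group mean. Adrb3 lies at 18.1 to 26.2 CPM in HFD_WT and at 194 to 350 CPM in HFD_TKO, while Cidea is at most 0.138 CPM in all TKO libraries.

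On ND, Cidea, Kcnj15, Adtrp and Ucp3 were lower and Sptlc3 and Plppr4 higher in TKO. Cidea, which encodes a lipid droplet protein also used as a marker of thermogenic fat (chromosome 18, 67343564 to 67367794), fell from 9.59 ± 1.69 CPM in ND_WT to 0.061 ± 0.0524 CPM in ND_TKO (log2 change -3.31, SE 0.18, adjusted p = 2.1e-06). The potassium channel gene Kcnj15 (chromosome 16, 95257558 to 95300260) fell from 169 ± 7.77 to 16.7 ± 2.45 CPM (-3.27, SE 0.18, adjusted p = 2.1e-06). Adtrp, a hydrolase of fatty acid esters of hydroxy fatty acids, fell from 9.80 ± 1.48 to 0.364 ± 0.129 CPM (-2.98, SE 0.14, adjusted p = 4.9e-07), and the mitochondrial carrier gene Ucp3 from 34.2 ± 1.13 to 6.61 ± 0.607 CPM (-2.21, SE 0.13, adjusted p = 2.1e-06). In the other direction Sptlc3, a subunit of the enzyme that starts sphingolipid synthesis, rose from 0.126 ± 0.12 CPM to 21.8 ± 1.41 CPM (4.34, SE 0.13, adjusted p = 8.0e-09), and Plppr4 rose from 1.46 ± 1.68 to 19.8 ± 3.53 CPM (3.28, SE 0.37, adjusted p = 5.4e-04). The mean of Sptlc3 in ND_WT and of Cidea in ND_TKO lay below the CPM of 3 reads, so these changes are set by the added 1 CPM.

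Genes of adipocyte metabolism went both ways on ND. Of 22 mature adipocyte genes 2 were higher and 4 lower (3 and 4 adjusted over the list alone), and of 22 genes of fatty acid and triglyceride synthesis 3 were higher and 5 lower (4 and 8 adjusted over the list alone); camera called neither list (adjusted p = 0.64 and 0.24). Resistin (Retn), an adipocyte hormone, fell from 1408 ± 92.2 to 699 ± 115 CPM (-1.02, SE 0.15, adjusted p = 0.0026). Mlxipl, the carbohydrate-responsive regulator of lipogenesis, fell from 83.6 ± 16.5 to 39.6 ± 2.68 CPM (-1.04, SE 0.13, adjusted p = 0.0011), Pck1, an enzyme of glyceroneogenesis, from 4124 ± 974 to 1902 ± 170 CPM, and the fatty acid elongase Elovl6 from 50.2 ± 18.7 to 15.1 ± 1.75 CPM. Acsl1, which activates fatty acids, rose from 2283 ± 421 to 4549 ± 290 CPM (1.01, SE 0.16, adjusted p = 0.0038). The insulin-responsive glucose transporter gene Slc2a4 fell by 0.60 (adjusted p = 0.026), a call that ended without ND_WT replicate 1 (adjusted p = 0.10) or ND_TKO replicates 1 (0.073), 2 (0.075) or 3 (0.059), and when only these groups were fitted (0.052). Adipoq, the adiponectin gene (0.33, adjusted p = 0.24; 0.032 with DESeq2), Adrb3, the main β-adrenergic receptor gene of adipocytes (-0.23, adjusted p = 0.60), and the lipase gene Pnpla2 (0.04, adjusted p = 0.92) did not pass the test.

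Extracellular matrix genes were higher in TKO on ND. Of 24 genes in the list 9 were higher and 1 was lower (11 and 3 adjusted over the list alone), with a median change of 0.38 (camera adjusted p = 2.2e-05; adjusted p = 0.91 with an estimated correlation). Lum, which encodes the collagen-binding proteoglycan lumican, rose from 67.2 ± 8.26 to 181 ± 16.7 CPM (1.42, SE 0.11, adjusted p = 4.3e-05), and the collagen gene Col6a1 from 364 ± 139 to 932 ± 289 CPM (1.38, SE 0.25, adjusted p = 0.0095; 0.060 when only these groups were fitted). Col1a1 differed by -0.49 and did not pass (adjusted p = 0.14). In total 337 genes were higher and 552 lower in TKO on ND, and 498 and 424 with TMM-scaled CPM. The total of 889 fell to 350 without ND_WT replicate 1, 506 without ND_WT replicate 2, 520 without ND_TKO replicate 1 and 435 without ND_TKO replicate 3, and was 1853 without ND_WT replicate 3; it was 280 when only these groups were fitted and 1400 with DESeq2. Camera called 8 lists in this comparison, 5 without ND_TKO replicate 3 and 3 without ND_WT replicate 3, where the matrix list had a median of 0.68, with 12 genes higher and 2 lower (adjusted p = 5.3e-08).

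On HFD, adipocyte genes were higher and immune cell genes lower in TKO than in WT. Adrb3 (chromosome 8, 27225776 to 27230845) stood at 23.3 ± 4.51 CPM in HFD_WT and 297 ± 89.3 CPM in HFD_TKO (log2 change 3.58, SE 0.23, adjusted p = 3.6e-07). The macrophage gene Adgre1, which encodes the surface protein F4/80, stood at 635 ± 83.1 CPM in HFD_WT and 68.3 ± 4.72 CPM in HFD_TKO (-3.19, SE 0.18, adjusted p = 1.7e-07). In total 2365 genes were higher and 4923 lower in HFD_TKO, and 3541 and 3853 with TMM-scaled CPM. Of these, 292 were higher and 1571 lower by at least 2-fold, and 420 and 1297 with TMM-scaled CPM.

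Of the 22 mature adipocyte genes 16 were higher and 1, Cidea, was lower in HFD_TKO (17 and 1 adjusted over the list alone), with a median change of 0.86 (camera adjusted p = 1.3e-08; adjusted p = 0.16 with an estimated correlation). Slc2a4 rose from 36.6 ± 2.84 in HFD_WT to 151 ± 28.1 CPM in HFD_TKO (adjusted p = 5.1e-07), Adipoq from 1429 ± 76.0 to 3948 ± 828 CPM (1.44, SE 0.16, adjusted p = 1.7e-05) and Retn from 114 ± 18.2 to 345 ± 51.7 CPM. Pparg, the master regulator of adipocyte differentiation, rose from 170 ± 6.45 to 235 ± 36.0 CPM (0.46, SE 0.11, adjusted p = 0.0037), while Cd36 (-0.08, adjusted p = 0.63) and Lep (-0.42, adjusted p = 0.50) did not pass. Cfd, the adipsin gene, was at 152 ± 26.9 and 388 ± 216 CPM (1.16, adjusted p = 0.060); the call was made without HFD_TKO replicate 1, with a change of 1.74 (adjusted p = 0.0034), with TMM-scaled CPM (1.29, adjusted p = 0.033), and with edgeR (0.017), DESeq2 (0.0051) and limma-voom (0.018). Among 19 genes of β-adrenergic signalling and lipolysis 11 were higher and 3 lower, the same adjusted over the list alone (median 0.54, camera adjusted p = 2.1e-04; adjusted p = 0.16 with an estimated correlation). The lipase genes Pnpla2 and Lipe and the lipid droplet gene Plin1 rose by 1.16, 0.84 and 0.87, whereas the adenylyl cyclase gene Adcy3 fell by 1.49. Of the 22 adipocyte genes 8 also belong to another list.

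Lipid synthesis and mitochondrial genes were higher as well. Of 22 genes of fatty acid and triglyceride synthesis 16 were higher and 1 lower (17 and 1 adjusted over the list alone; median 0.85, camera adjusted p = 5.0e-08; adjusted p = 0.16 with an estimated correlation). Thrsp, a lipogenic regulator, rose from 122 ± 18.4 to 1007 ± 42.9 CPM (3.05, SE 0.15, adjusted p = 6.6e-08), Mlxipl by 1.16, Fasn, the fatty acid synthase gene, by 0.95 and Acly by 0.77. All 26 tested nuclear genes of oxidative phosphorylation were higher, also adjusted over the list alone, by a median of 0.39 (camera adjusted p = 7.1e-11; adjusted p = 0.25 with an estimated correlation); Ndufv1 of complex I rose by 0.59 and Uqcrfs1 of complex III by 0.57. Of 21 genes of mitochondrial fatty acid oxidation 15 were higher and 1 lower, the same adjusted over the list alone (median 0.41, camera adjusted p = 1.1e-06; adjusted p = 0.34 with an estimated correlation) and Acads rose by 0.72. Cyp2e1, a cytochrome P450 gene abundant in adipocytes (chromosome 7, 140763819 to 140774990), rose from 18.7 ± 9.08 to 887 ± 133 CPM (5.59, SE 0.42, adjusted p = 9.1e-07).

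Genes of immune cells were lower in HFD_TKO. Of 20 macrophage genes 17 were lower and 2, Cd163 and Lyve1, were higher, the same adjusted over the list alone (median -2.08, camera adjusted p = 4.5e-07; adjusted p = 0.22 with an estimated correlation). Of 18 genes of lipid-associated macrophages, which gather around dying adipocytes in obesity, 16 were lower and none higher, the same adjusted over the list alone (median -2.32, camera adjusted p = 4.5e-07; adjusted p = 0.20 with an estimated correlation). Itgax, which encodes CD11c, stood at 318 ± 40.4 CPM in HFD_WT and 24.7 ± 0.987 CPM in HFD_TKO (-3.63, SE 0.26, adjusted p = 6.8e-07), and Trem2 at 200 ± 28.2 and 17.8 ± 3.61 CPM (-3.43, SE 0.31, adjusted p = 3.3e-06). Of 21 cytokine and chemokine genes 14 were lower (15 adjusted over the list alone; median -1.32, camera adjusted p = 3.0e-04; adjusted p = 0.16 with an estimated correlation); Tnf fell from 2.50 ± 0.772 to 0.539 ± 0.299 CPM and Ccl2 from 20.9 ± 3.69 to 11.5 ± 2.22 CPM. Lower members numbered 15 of 17 T and NK cell genes (median -1.39, camera adjusted p = 0.0011), 9 of 9 B and plasma cell genes (-2.26, 0.0069) and 14 of 19 interferon response genes (-0.66, 0.0045), or 15, 9 and 16 adjusted over the list alone. Each of these 3 lists had an adjusted p of 0.66 with an estimated correlation. Of 10 granulocyte and mast cell genes 8 were lower, the same adjusted over the list alone (-2.10, camera adjusted p = 2.6e-04; adjusted p = 0.16 with an estimated correlation), and Cpa3 of mast cells fell by 3.40.

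All 18 cell cycle genes were lower in HFD_TKO, also adjusted over the list alone (median -1.56, camera adjusted p = 2.8e-09; adjusted p = 0.21 with an estimated correlation). Pcna, the replication clamp gene, fell from 146 ± 1.25 to 53.3 ± 6.67 CPM (-1.44, SE 0.09, adjusted p = 2.7e-07), and Mcm6 of the replicative helicase by 1.78. Matrix genes went both ways, with 3 of 24 higher and 10 lower, the same adjusted over the list alone (camera adjusted p = 0.31). Lum fell by 1.15, Col1a1 by 0.95 and the matrix metalloprotease gene Mmp14 by 1.97, while Timp1 fell from 33.5 ± 4.57 to 10.5 ± 2.64 CPM. Of 18 endothelial and mural genes 4 were higher and none lower (3 and 0 adjusted over the list alone; median 0.11, camera adjusted p = 0.063); with TMM-scaled CPM 9 were higher and the list was called (median 0.25, adjusted p = 0.023; adjusted p = 0.63 with an estimated correlation). It was also called without ND_WT replicate 3 (0.047), HFD_WT replicate 3 (0.027) or HFD_TKO replicates 2 (0.043) or 3 (0.020). Of 18 stromal genes 3 were higher and 8 lower (4 and 8 adjusted over the list alone; median -0.14, camera adjusted p = 0.57). None of 11 mesothelial genes passed (-0.05, camera adjusted p = 0.57), and that list was called without HFD_TKO replicate 1 (adjusted p = 0.011).

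A subset of genes differed between genotypes under both diets. Of 889 genes called on ND and 7288 called on HFD, 182 were higher and 275 lower in TKO under both, against 51.1 and 174 for independent lists; 105 had opposite signs. With TMM-scaled CPM 271 were higher and 187 lower, so which direction held more genes depended on the scaling. These comparisons share no library. The count of 457 with the same sign ranged from 194 without ND_WT replicate 1 to 847 without ND_WT replicate 3, with 264 without ND_WT replicate 2, 266 and 212 without ND_TKO replicates 1 and 3, and 292 without HFD_WT replicate 1. Cidea fell on HFD by 2.11 (3.88 ± 1.23 to 0.108 ± 0.0258 CPM, below the CPM of 3 reads), Kcnj15 from 87.4 ± 10.8 to 12.9 ± 4.35 CPM, Adtrp by 2.86 and Ucp3 by 2.06, and Plppr4 rose by 3.26. The differences of the TKO effect between diets for Kcnj15 (0.56, adjusted p = 0.13), Adtrp (0.12, adjusted p = 0.68), Ucp3 (0.15, adjusted p = 0.57) and Plppr4 (-0.01, adjusted p = 0.99) did not pass the main test. For Kcnj15 it passed without HFD_TKO replicate 1 (0.77, adjusted p = 0.019) and with DESeq2 (adjusted p = 0.031) or a pseudocount of 5 (0.048). Around Cidea, Gnal, Mppe1, Impa2 and B430212C06Rik were also lower, with changes of -1.25, -0.55, -0.47 and -2.28 on ND and of -3.29, -1.58, -1.07 and -2.70 on HFD. They were chosen after their values were seen, and Chmp1b, inside Gnal, was not called on ND (0.04, adjusted p = 0.85). On ND the call of Impa2 (adjusted p = 0.049) ended without each of ND_WT replicates 1 or 2 or ND_TKO replicates 1, 2 or 3 (0.090 to 0.16), and with edgeR (0.092), DESeq2 (0.085), limma-voom (0.089), TMM-scaled CPM (0.063) and only these groups fitted (0.14). That of Gnal ended without ND_WT replicate 1 (0.067) or ND_TKO replicates 1 (0.055) or 3 (0.052) and with only these groups fitted (0.084), and that of Mppe1 ended without ND_WT replicates 1 (0.083) or 2 (0.064) or ND_TKO replicates 1 (0.070) or 3 (0.068) and with only these groups fitted (0.077). B430212C06Rik overlaps Cidea and Gnal overlaps Mppe1, so their reads are uncertain.

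**Figure D2:**
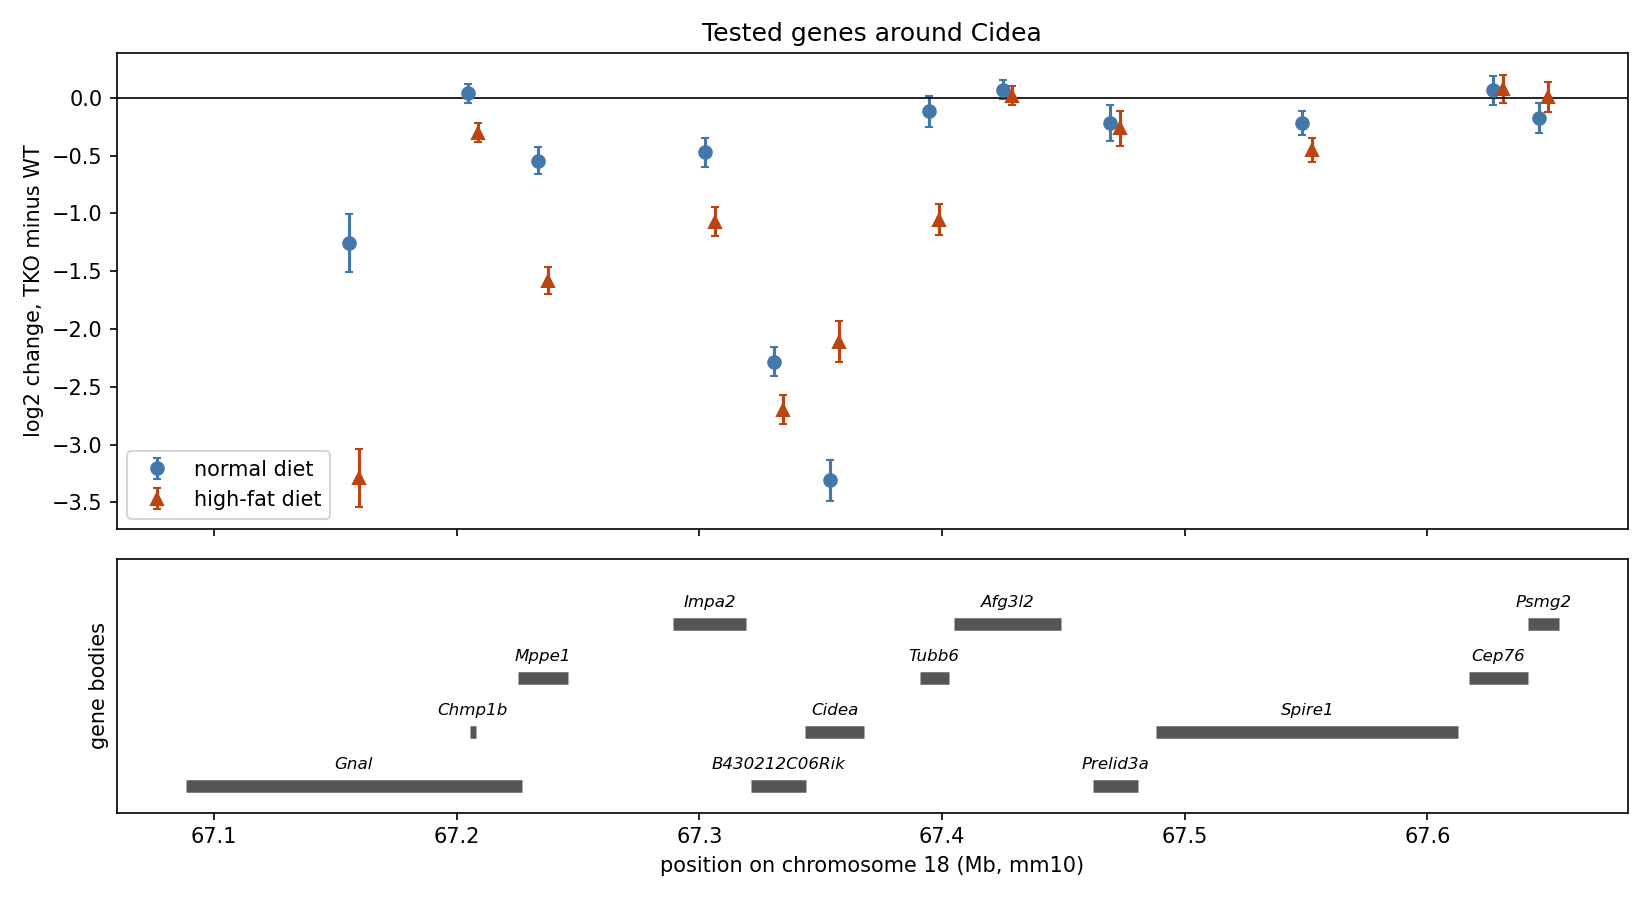
Log2 change ± SE in TKO against WT on ND and on HFD for 12 tested genes around Cidea on chromosome 18 of mm10, with gene bodies to scale along the chromosome. Cidea changes by -3.31 and -2.11 and Gnal by -1.25 and -3.29, while Afg3l2 changes by 0.07 and 0.02.

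HFD in WT mice lowered adipocyte genes and raised immune, matrix and cell cycle genes. Adrb3 fell from 694 ± 147 to 23.3 ± 4.51 CPM (log2 change -4.83, SE 0.23, adjusted p = 2.4e-08) and Cyp2e1 from 7143 ± 3858 to 18.7 ± 9.08 CPM (-8.43, SE 0.42, adjusted p = 2.9e-08). Adgre1 rose from 39.7 ± 0.924 to 635 ± 83.1 CPM (3.96, SE 0.18, adjusted p = 1.8e-08) and Itgax from 9.17 ± 3.21 to 318 ± 40.4 CPM (5.01, SE 0.26, adjusted p = 3.4e-08). In total 5892 genes were higher and 3173 lower, and 4550 and 4395 with TMM-scaled CPM.

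Of 22 mature adipocyte genes 19 were lower on HFD in WT and 1, Lep, was higher, the same adjusted over the list alone (median -1.16, camera adjusted p = 1.9e-10; adjusted p = 0.14 with an estimated correlation). Cfd fell by 5.89, Retn by 3.63, Slc2a4 by 2.66, Adipoq by 1.76, and the lipase gene Lipe by 1.67. Pnpla2 fell from 2691 ± 515 to 662 ± 31.8 CPM. Lep was higher by 1.62 (adjusted p = 0.011), a call that edgeR (adjusted p = 0.081) and DESeq2 (0.11) did not make. Lower members numbered 23 of 26 oxidative phosphorylation genes (median -0.54, camera adjusted p = 1.9e-10), 14 of 21 fatty acid oxidation genes with 2 higher (-0.44, 4.9e-05), 13 of 22 lipid synthesis genes (-0.91, 2.1e-05) and 12 of 19 β-adrenergic and lipolysis genes with 2 higher (-0.50, 3.6e-05). Adjusted over the list alone the lower members were 24, 14, 13 and 12. With an estimated correlation these 4 lists had an adjusted p of 0.27, 0.44, 0.25 and 0.095. Pck1 fell by 3.66 and Thrsp by 3.05. Cholesterol synthesis went the other way, with 17 of 19 genes higher, the same adjusted over the list alone (median 1.11, camera adjusted p = 3.9e-04; adjusted p = 0.45 with an estimated correlation): Insig1, a sterol sensor, rose by 1.81 and Dhcr7 by 2.27. Of 20 insulin signalling genes 6 were higher and 11 lower (6 and 12 adjusted over the list alone; -0.57, camera adjusted p = 0.011; adjusted p = 0.45 with an estimated correlation).

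Immune lists rose on HFD in WT, though that of B and plasma cells was not called (camera adjusted p = 0.094). Higher members numbered 17 of 20 macrophage genes (median 2.39, camera adjusted p = 1.5e-06), 17 of 18 lipid-associated macrophage genes with 1 lower (2.92, 6.1e-07), 17 of 21 cytokine genes (1.78, 4.9e-05), 14 of 17 T and NK cell genes (1.48, 0.0030) and 9 of 10 granulocyte and mast cell genes (1.94, 0.0030). Adjusted over the list alone the higher members were 17, 17, 17, 15 and 9. With an estimated correlation these 5 lists had an adjusted p of 0.25, 0.22, 0.16, 0.57 and 0.22. The lipid-associated macrophage genes Gpnmb, Mmp12 and Atp6v0d2 rose by 5.02, 5.21 and 5.30. All 18 cell cycle genes (2.21, camera adjusted p = 5.5e-10) and 23 of 24 matrix genes (1.51, 1.0e-06) were higher, the same adjusted over the list alone, with an adjusted p of 0.22 and 0.33 with an estimated correlation. Top2a rose from 6.00 ± 0.697 to 62.4 ± 3.86 CPM, Lum by 2.83 and Timp1 by 2.88. Of 19 interferon response genes 13 were higher, the same adjusted over the list alone (0.57, camera adjusted p = 0.0498; adjusted p = 0.67 with an estimated correlation), a list call that ended without ND_WT replicates 2 (adjusted p = 0.081) or 3 (0.097) or HFD_WT replicate 3 (0.15). Mesothelial genes were lower in 7 of 11 (9 adjusted over the list alone; -1.39, camera adjusted p = 0.0016; adjusted p = 0.49 with an estimated correlation).

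In TKO mice HFD also lowered adipocyte genes and raised macrophage genes. Adrb3 fell from 583 ± 57.9 to 297 ± 89.3 CPM (log2 change -1.02, SE 0.23, adjusted p = 0.010), Adgre1 rose from 31.2 ± 10.1 to 68.3 ± 4.72 CPM (1.15, SE 0.18, adjusted p = 0.0020) and Itgax from 10.7 ± 5.15 to 24.7 ± 0.987 CPM (1.22, SE 0.26, adjusted p = 0.0076). Slc2a4 stood at 156 ± 9.92 and 151 ± 28.1 CPM (-0.06, SE 0.14, adjusted p = 0.79). In total 2525 genes were higher and 921 lower, and 1520 and 1394 with TMM-scaled CPM. The total of 3446 was 1716 without ND_TKO replicate 3 and 2220 without HFD_TKO replicate 3.

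Of 22 mature adipocyte genes 12 were lower and 1, Lep, higher on HFD in TKO, the same adjusted over the list alone (median -0.47, camera adjusted p = 9.4e-09; adjusted p = 0.22 with an estimated correlation). Cfd fell by 2.59, Retn by 1.02, Pnpla2 by 0.88 and Lipe by 0.72. Adipoq fell by 0.65 (adjusted p = 0.014), a call that ended without ND_TKO replicate 3 (adjusted p = 0.059) and with no filter (0.062). Lep was higher by 1.62 (adjusted p = 0.030), a call that ended without ND_TKO replicates 2 (0.085) or 3 (0.10) or HFD_TKO replicates 1 (0.096), 2 (0.0502) or 3 (0.057), and with edgeR (0.053) or no filter (0.053). Of 19 cholesterol synthesis genes 17 were higher (17 and 1 lower adjusted over the list alone; median 1.02, camera adjusted p = 7.8e-07; adjusted p = 0.38 with an estimated correlation): Sc5d rose by 1.48 and Insig1 by 1.24. Lipid synthesis genes were split, 9 of 22 higher and 5 lower (10 and 5 adjusted over the list alone; camera adjusted p = 0.73). Acly rose from 201 ± 15.8 to 572 ± 76.9 CPM (adjusted p = 0.0013) and the desaturase gene Scd2 from 322 ± 40.6 to 1247 ± 432 CPM, whereas Pck1 fell by 1.44. Of 26 oxidative phosphorylation genes 7 were lower (-0.16, camera adjusted p = 5.5e-06), of 19 β-adrenergic genes 7 (-0.31, 7.4e-05), and of 21 fatty acid oxidation genes 8, with 2 higher (-0.06, 0.016), the same adjusted over the list alone. With an estimated correlation these 3 had an adjusted p of 0.50, 0.11 and 0.69. The fatty acid oxidation list lost its call without ND_TKO replicate 3 (adjusted p = 0.054) or HFD_TKO replicates 2 (0.11) or 3 (0.14).

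Higher members on HFD in TKO numbered 12 of 20 macrophage genes (median 0.72, camera adjusted p = 5.5e-06), 10 of 18 lipid-associated macrophage genes (0.97, 0.0015), 8 of 21 cytokine genes (0.57, 0.015), 16 of 18 cell cycle genes (0.77, 2.2e-09) and 14 of 24 matrix genes (0.56, 2.5e-05). Adjusted over the list alone they were 15, 11, 9, 17 and 16. With an estimated correlation the lists had an adjusted p of 0.38, 0.47, 0.38, 0.38 and 0.50, and the cytokine list lost its call without HFD_TKO replicate 1 (adjusted p = 0.054). Trem2 rose by 1.48, Ccl2 by 1.61, Top2a by 1.34 and Col6a3 by 1.52. None of 17 T and NK cell genes was called. Of 20 insulin signalling genes 3 were higher and 1 lower, the same adjusted over the list alone, although camera placed the list lower (median -0.12, camera adjusted p = 0.033; adjusted p = 0.57 with an estimated correlation). That list call ended without ND_TKO replicate 2 (adjusted p = 0.0504) or HFD_TKO replicate 1 (0.087), and its members were 1 higher and 2 lower with TMM-scaled CPM and 3 higher and 7 lower without ND_WT replicate 3.

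**Figure D3:**
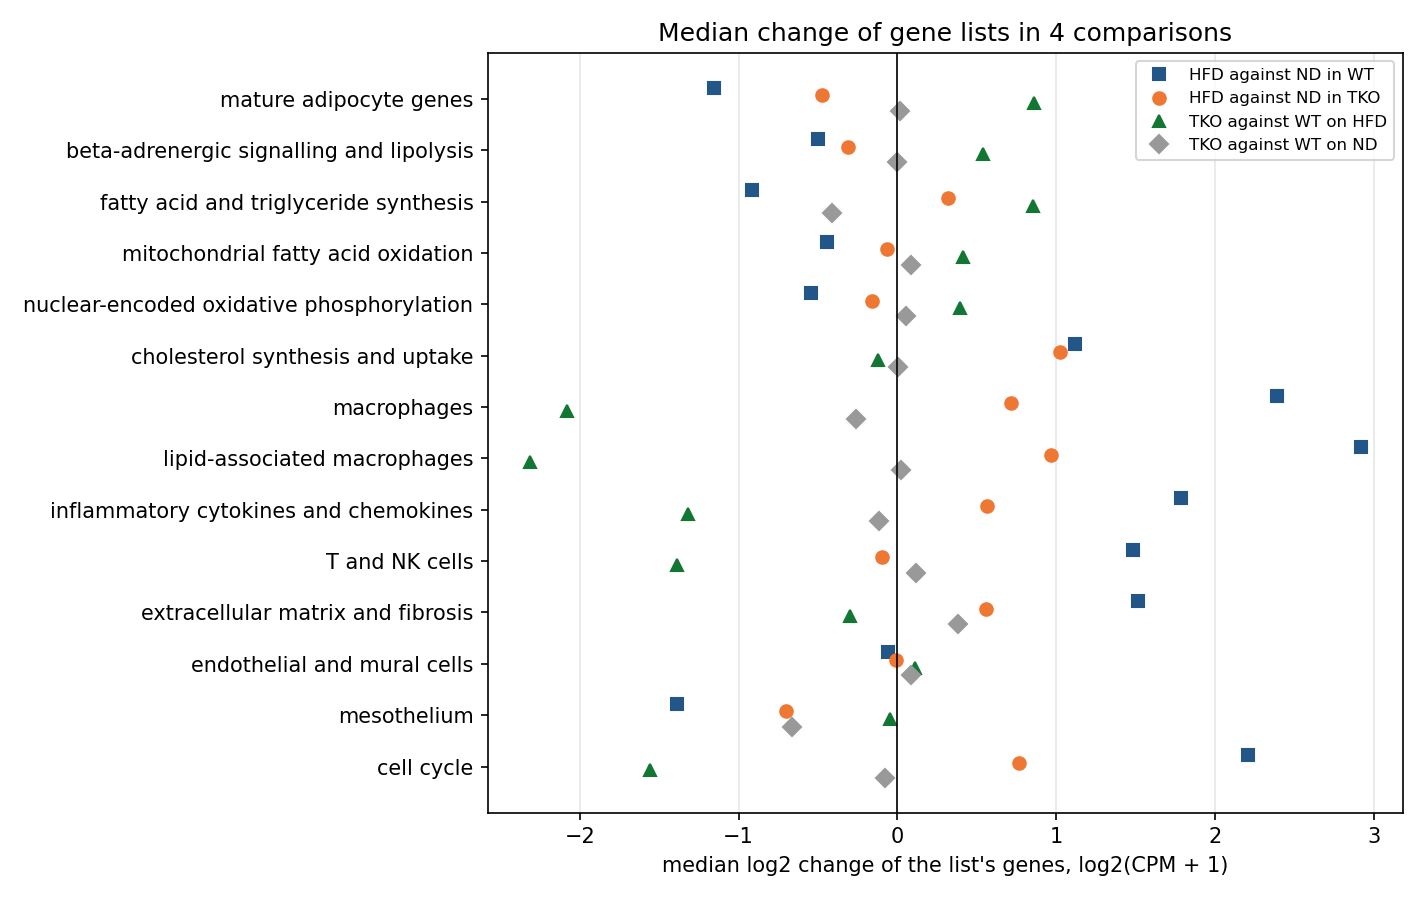
Median log2 change, on the log2(CPM + 1) scale, of the tested genes of 14 lists in the comparisons of diet within each genotype and of genotype within each diet. The median of lipid-associated macrophage genes is 2.92 for HFD in WT and 0.97 for HFD in TKO, and that of mature adipocyte genes is -1.16 and -0.47.

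The difference of the TKO effect between the diets was tested as the genotype by diet interaction, which equals the difference of the diet effect between genotypes. For Adrb3 it was 3.81 (SE 0.33, adjusted p = 1.6e-05), for Slc2a4 2.60 (SE 0.19, adjusted p = 7.8e-06) and for Adipoq 1.11 (SE 0.22, adjusted p = 0.0032). For Itgax it was -3.79 (SE 0.37, adjusted p = 3.0e-05), for Adgre1 -2.81 (SE 0.26, adjusted p = 2.1e-05) and for Lum -2.57 (SE 0.16, adjusted p = 2.6e-06). In total 1550 genes had a positive and 2926 a negative interaction, and 1987 and 2533 with TMM-scaled CPM. Camera called 13 lists: those of adipocyte genes, lipid synthesis, fatty acid oxidation, oxidative phosphorylation and β-adrenergic signalling were positive, and the lists of 6 immune groups, matrix and cell cycle negative. With an estimated correlation their adjusted p lay between 0.12 and 0.71.

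Most genes that HFD raised in WT and that also differed by genotype on HFD were lower in TKO. Of 5657 genes called in both comparisons 5500 had opposite signs: 4005 were higher in HFD_WT than in ND_WT and lower in HFD_TKO than in HFD_WT, which is 68.0% of the 5892 raised genes, and 1495 the reverse, 47.1% of the 3173 lowered genes. With TMM-scaled CPM the numbers were 3065 and 2447. Both comparisons use the HFD_WT libraries. In 100 simulations of unchanged groups that shared those libraries the mean number with opposite signs was 0.01 and the highest 1. As no gene was changed in them, hardly any could be called, so that number was near 0 in advance and gives no baseline. Independent lists would give 1860 and 481. Part of the excess over the numbers for independent lists can come from the shared libraries. The covariance of the log2 changes across genes was -0.45, against -0.015 in the simulations, a difference of -0.44. Among genes higher in HFD_WT than in ND_WT the median diet response was 0.71 in WT and 0.25 in TKO, and among lower genes -0.63 and -0.20; these sets were selected on the WT response, which enlarges it. Of the 5892 and 3173 genes, 2003 and 726 were also called in TKO with the same sign. With TMM-scaled CPM these were 1186 of 4550 and 1141 of 4395, so the difference between the directions depended on the scaling.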

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

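Chosen only after the result was seen were the lists without single libraries, the tests of the adipocyte pattern, the tests around Cidea, and the tests of whether ND_WT replicate 3 is a TKO library or holds TKO RNA. The results listed here are those in which the effect of TKO differed between the diets by the interaction test of limma, which 4476 genes passed. In 100 assignments of the 12 libraries to 4 groups, only the real one (1 of 100) reached that count. The highest other assignment gave 3135 genes, and the cause of that number was not tested. The 5500 genes with opposite signs for HFD in WT and TKO on HFD were likewise reached by 1 of 100 assignments, the highest other giving 1. Such assignments remove the diet and genotype differences together and move them into the spread. They therefore test neither the interaction alone nor the opposite signs themselves. For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05: 1 of 10 splits, the real one, reached 889 (TKO on ND), 7288 (TKO on HFD), 9065 (HFD in WT) and 3446 genes (HFD in TKO), and the highest other split gave 0 genes in each. Every other split mixes libraries of both groups, which moves the real difference into the spread. Few or no calls were therefore likely in advance, and the 0 gives no baseline.

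Gene lists with an interaction were 13, all without a call under an estimated correlation. The median interaction was positive for genes of mature adipocytes (0.92; 13 of 22 higher, 1 lower), lipid synthesis (1.17; 14 of 22), oxidative phosphorylation (0.36; 15 of 26), fatty acid oxidation (0.30; 9 of 21, 1 lower) and β-adrenergic signalling and lipolysis (0.26; 8 of 19, 2 lower). It was negative for macrophages (-1.69; 15 of 20 lower, 1 higher), lipid-associated macrophages (-2.23; 17 of 18, 1 higher), cytokines (-1.09; 11 of 21), T and NK cells (-1.56; 11 of 17), B and plasma cells (-2.10; 3 of 9), granulocytes and mast cells (-1.93; 7 of 10), matrix (-0.71; 11 of 24) and cell cycle (-1.44; 18 of 18). Adjusted over the list alone the counts of the leading direction were 14, 16, 16, 10 and 8 for the positive lists and 16, 17, 11, 14, 4, 8, 12 and 18 for the negative lists. Their adjusted p with an estimated correlation was 0.12, 0.12, 0.39, 0.52 and 0.12 for the positive lists, and 0.18, 0.12, 0.12, 0.52, 0.71, 0.12, 0.52 and 0.14 for the negative lists. Other lists were called when a single library was left out: the clock list without ND_WT replicate 3, ND_TKO replicates 2 or 3, HFD_WT replicate 2 or HFD_TKO replicate 1 (adjusted p = 0.019 to 0.047), mesothelium without ND_TKO replicate 3 (0.045) or HFD_TKO replicate 1 (1.0e-04), insulin signalling without ND_WT replicate 3 (0.031), interferon response without HFD_WT replicate 2 (0.016), immediate early genes without HFD_WT replicate 3 (0.021) and cholesterol synthesis without HFD_TKO replicate 1 (0.017).

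Among adipocyte, lipolysis and lipid synthesis genes the interaction was 3.81 for Adrb3, 1.11 for Adipoq, 3.30 for Cfd, 2.61 for Retn, 2.60 for Slc2a4, 1.12 for Pnpla2, 0.95 for Lipe, 0.88 for Plin1, 0.62 for Pparg, 1.199 for Cidea, -0.72 for Acsl1 and -1.34 for Adcy3. It was 3.31 for Thrsp, 2.21 for Mlxipl, 2.22 for Pck1, 1.86 for Fasn, 1.498 for Acly, 1.71 for Scd1, 1.01 for Elovl6 and 6.47 for Cyp2e1. Mitochondrial genes had 0.51 (Acads), 0.60 (Echs1), 0.46 (Ndufv1), 0.62 (Ndufb8) and 0.45 (Uqcrfs1), and sterol genes -0.49 (Srebf2) and 0.84 (Sc5d). The mean of Cidea lies below the CPM of 3 reads in ND_TKO and HFD_TKO (0.061 and 0.108 CPM), so its interaction is set by its level in WT, and was not called by edgeR (adjusted p = 0.069), DESeq2 (0.077) or limma-voom (0.11). The call of Scd1 ended without a filter (0.46). The call of Acsl1 ended with edgeR (0.065), limma-voom (0.057), TMM-scaled CPM (0.081) and no filter (0.093), and without ND_TKO replicates 2 or 3, HFD_WT replicates 1 or 2 or HFD_TKO replicates 2 or 3 (0.065 to 0.082). That of Sc5d ended without ND_WT replicates 1 or 3, ND_TKO replicates 2 or 3 or HFD_WT replicate 3 (0.051 to 0.067).

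Among macrophage and other immune genes the interaction was -2.81 for Adgre1, -2.49 for Cd68, -3.79 for Itgax, -2.91 for Trem2, -3.75 for Gpnmb, -3.62 for Mmp12, -3.51 for Atp6v0d2 and -4.38 for Itgad. It was -0.96 for Ccl2, -1.09 for Tnf, -1.62 for Casp1, -2.58 for Cd8a, -4.37 for Jchain and -2.51 for Cpa3, but 3.04 for Retnla, 2.80 for Mgl2, 0.95 for Cd163, 4.96 for Rnase2a and 4.53 for Orm3. The call of Cd163 ended without ND_WT replicates 2 or 3, ND_TKO replicates 1 or 3, HFD_WT replicates 1, 2 or 3 or HFD_TKO replicates 2 or 3 (adjusted p = 0.066 to 0.10), and with no filter (0.070). That of Tnf ended with edgeR (0.062), DESeq2 (0.057) and limma-voom (0.052), and that of Ccl2 with limma-voom (0.079).

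Matrix genes had -2.57 (Lum), -1.86 (Timp1) and -1.43 (Mmp14). Genes of the cell cycle and of DNA methylation had -1.25 (Pcna), -1.61 (Mcm6), -1.84 (Top2a), -1.26 (Dnmt1), -0.97 (Dnmt3a), -1.38 (Uhrf1), -1.05 (Gadd45g) and -0.40 (Tet3). The remaining genes had -2.94 (Mest), -3.09 (Sptlc3), 1.04 (Art3), -3.76 (Tph2), 1.43 (Nr1d1) and 1.06 (Dbp). The call of Tet3 ended with edgeR (adjusted p = 0.064), DESeq2 (0.054), limma-voom (0.068) and TMM-scaled CPM (0.064), and without ND_WT replicate 2, ND_TKO replicates 1 or 2, HFD_WT replicates 2 or 3 or HFD_TKO replicates 1, 2 or 3 (0.051 to 0.083). That of Gadd45g ended without ND_TKO replicates 2 or 3, HFD_WT replicate 3 or HFD_TKO replicates 1 or 2 (0.051 to 0.068). The call of Tph2 ended with edgeR (0.38), limma-voom (0.22) and a pseudocount of 0.1 (0.0501).

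Mature adipocyte genes were higher in HFD_TKO than in HFD_WT, and a smaller share of immune cells is a candidate explanation. Fewer immune cells would raise the markers of all other cell types alike, but the adipocyte list rose by 0.73 more than the endothelial and mural list (95% interval 0.42 to 1.04), and by 1.07 more than the stromal list (0.73 to 1.42); against mesothelium the interval (-0.20 to 1.96) held 0. A larger share of adipocytes with no other change would move members made by adipocytes alone by an equal amount. Of the 22 members 13 deviated from the mean of the list, 6 above (Adrb3 and Car3 most) and 7 below. That count cannot decide, because members also made by immune cells would fall with those cells. Cidea, which was lower on ND as well, also pulled the mean down (deviation -2.98). With TMM factors the median of the list was 0.99, against 0.86 on CPM. TMM moved all genes of this comparison by about 0.14, so the median could not drop to 0. This shows only that the choice of CPM over TMM did not cause the rise. The values thus argue against fewer immune cells as the whole cause, and against the choice of CPM over TMM. They leave a larger share of adipocytes open. The explanations were not tested together, and cell shares were not measured. Altered expression in adipocytes of TKO mice on HFD stays a hypothesis, found on the same libraries, that these values do not separate from altered cell shares.

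Gnal, Mppe1, Impa2, B430212C06Rik and Cidea, lowered under both diets, lie together on chromosome 18 between 67088298 and 67367794. That stretch held 6 tested genes. The remaining one, Chmp1b, lies inside Gnal and was not called on ND (0.04, adjusted p = 0.85), and it fell by 0.30 on HFD (adjusted p = 0.0087). A count fixed before its result, of lowered genes with a lowered neighbour at 10 to 100 kb across the genome, was within chance (22 of 269 genes, random median 16; reached by a share of 0.15 of random sets). The test of this region, chosen afterwards, found 5 lowered genes within 300 kb in a share of 0.003 of 2000 random sets, but 4 genes, without Impa2, in 0.078, and 3 separate genes, with overlapping genes taken as 1, in 0.66. Chance placement and reads shared between overlapping genes therefore cannot be told apart from a change of the region. DNA of another strain linked to the Tet alleles is argued against by 0 of 5 genes within 10 Mb of Tet1, Tet2 or Tet3, which lie on chromosomes 10, 3 and 6. Strain DNA not linked to these alleles was not tested and stays open. The insertion site of the recombinase was not given in the labels and stays open as well.

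ND_WT replicate 3 lay apart from ND_WT replicates 1 and 2 and moved the count on ND from 889 to 1853 when left out. A TKO library under a WT label was first tested by the median position of the library between ND_WT and ND_TKO over 140 genes; that came out at 0.44, too near its bound to decide, and was replaced by another test. In the later test the library lay beyond all ND_TKO libraries on the WT side in 77.1% of those genes, against 25% for a TKO library. The 25% holds for genes not selected on these libraries. The 140 genes were selected by the difference of the ND_TKO libraries from ND_WT replicates 1 and 2. A TKO library could thus exceed 25%, by an amount that was not measured. Across all genes, however, it correlated better with ND_TKO replicates 1 and 3 (0.988 and 0.986) than with ND_WT replicates 1 and 2 (0.983 and 0.982). Its correlation with ND_TKO replicate 2 was lower (0.980). TKO RNA mixed into ND_WT replicate 3 was tested in 3 versions. Those by Sptlc3 alone and by a count that a WT library could hardly reach were dropped. In the last version 42.1% of the 140 genes lay outside the range of a mix at the best share (0.50), and 61.4% with no mix. In the other ND libraries at most 29.5% did so. Each of those had its own set of 69 to 97 genes, so the percentages are not like for like and do not decide. Sptlc3 allowed a share of at most 0.66%, while other raised genes allowed 19.7% (Plppr4) to 89.4% (Mageb18). Kcnj15 stood at 160 CPM, against 172 and 174 in ND_WT replicates 1 and 2. Ucp3 stood at 35.5 CPM (33.4 and 33.6) and Cidea at 7.80 CPM (9.82 and 11.2), though H2-Q10 (10.7 against 38.1 and 35.4) lay toward TKO. A share of TKO RNA would hold for all genes of the library. Sptlc3, Kcnj15, Ucp3 and Cidea thus argue against a mix at the best share of 0.50, while H2-Q10 does not. The tightest bound, 0.66%, rests on Sptlc3 alone, and the test over the 140 genes does not decide. A mix at a smaller share therefore stays open. An HFD library under an ND label is argued against by a median diet position of 0.15 (0 is ND_WT, 1 is HFD_WT; 2957 genes), while its deviation correlated with the change that HFD made in TKO across 15597 genes (r = 0.41; genes are not independent replicates), so a difference of body fat or feeding of that mouse could be a source, which was not tested.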

How the results depend on the processing

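Chosen only after the data were seen were edgeR with TMM factors, TMM-scaled CPM, the lists without single libraries, the replicate block among TKO libraries and the alternatives of the overlap between diets. Of 252 results of named genes, 204 kept direction and side of the threshold under all alternatives run. Of 4740 alternative values 4533 did so, 154 lost the call, 53 gained one and 0 changed direction. Against 889, the count on ND was 1400 with DESeq2 and 280 with only the groups compared. The latter fit has fewer libraries for the spread. It gave 7683 against 7288 genes for TKO on HFD, 8943 against 9065 for HFD in WT and 2665 against 3446 for HFD in TKO. The cause of either difference on ND was not tested. Genes changed the same way in both diets were 457, and 688 with DESeq2; the cause was not tested. Leaving out single libraries gave 350 to 1853 genes for TKO on ND, 6103 to 6784 on HFD, 7897 to 9138 for HFD in WT, 1716 to 3046 for HFD in TKO, 3541 to 5041 with an interaction, 4650 to 5509 with opposite signs, and 194 to 847 for both diets. Called lists were 67 over the 5 contrasts (64 to 71 without single libraries): 8 (3 to 9), 13 (13 to 15), 18 (17 to 19), 15 (13 to 15) and 13 (13 to 16). Camera with an estimated correlation called 0 in total, and 0 for TKO on ND, 0 for TKO on HFD, 0 for HFD in WT, 0 for HFD in TKO and 0 for the interaction, with 0, 6, 6, 3 and 7 at an unadjusted p under 0.05; the cause was not tested. Fry called 0, 18, 23, 10 and 12 lists in 1 direction in that order, and in either direction 113 in total, 17 on ND, 26 on HFD and 21 for the interaction. Of 18 pairs with the same replicate number 5 had a correlation over 0.1 (-0.50 to 0.56), 3 of them all those between ND_TKO and HFD_TKO, and 4 of 12 libraries correlated best with their own number. With a replicate block among the TKO libraries HFD in TKO had 3825 genes (3328 shared with the 3446, in the same direction) and 15 lists, and of the named genes Fasn (adjusted p = 0.052) and Retnla (0.056) lost their call. With the replicate block the counts were 751, 7114, 8921, 3162 and 4228 genes, 68 lists (the interaction of the clock list was gained, adjusted p = 0.049), 5375 with opposite signs and 391 for both diets. Of named genes, Impa2 on ND (0.082) and the interaction of Tet3 (0.055) lost their call under that block, and the interactions of Lyve1 (0.044), Thbs1 (0.038) and Tmem45b (0.038) gained one. Depth limits low genes: a count of 0 allows up to 3 reads, or 0.117 to 0.143 CPM per library.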

Other observations

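Chosen only after the values were seen were Cd163, Lyve1, Mgl2 and Retnla as genes to name outside the interaction, and all list tests without single libraries. A few macrophage genes went against the rest of their class on HFD. Retnla, a gene of alternatively activated macrophages, stood at 87.2 ± 47.4 CPM in HFD_WT and 575 ± 78.7 CPM in HFD_TKO (log2 change 2.82, SE 0.37, adjusted p = 7.3e-05), and the lectin gene Mgl2 at 14.0 ± 0.485 and 80.3 ± 16.9 CPM (2.41, SE 0.20, adjusted p = 1.6e-06). Rnase2a, an eosinophil-associated ribonuclease gene also made by macrophages, rose from 0.106 ± 0.147 to 50.9 ± 16.7 CPM (5.51, SE 0.37, adjusted p = 4.5e-07); its mean in HFD_WT lies below the CPM of 3 reads, so the change is set by the added 1 CPM. Cd163 and Lyve1, genes of resident macrophages, rose by 1.03 (adjusted p = 0.0028) and 0.93 (adjusted p = 0.012), while Adgre1 fell by 3.19. Cd163 and Lyve1 were the only 2 of 20 macrophage genes that were higher, and 17 were lower. Mrc1, Timd4 and Clec10a of that list were not higher, and resident macrophage genes were not tested as a set. For Lyve1 the difference of the TKO effect between diets did not pass the main test (0.85, adjusted p = 0.11). It passed without ND_WT replicate 1 (1.09) or ND_TKO replicate 2 (1.13), with the replicate block (adjusted p = 0.044) and with DESeq2 (adjusted p = 0.029).

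Of 16 tested genes of DNA methylation and demethylation enzymes 10 were higher and 1 lower on HFD in WT, the same adjusted over the list alone (camera adjusted p = 0.082), and 10 were higher and 1 lower on HFD in TKO (11 and 1 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.38 with an estimated correlation). On HFD 2 were higher and 7 lower in TKO (2 and 8 adjusted over the list alone; camera adjusted p = 0.57). With TMM-scaled CPM 8 were higher and 3 lower on HFD in WT, 6 and 1 on HFD in TKO, and 5 and 6 in TKO on HFD. Dnmt3a, a de novo methyltransferase gene, rose on HFD from 37.6 ± 5.36 to 151 ± 12.6 CPM in WT (1.98, adjusted p = 1.2e-07) and by 1.01 in TKO (adjusted p = 0.0010). Dnmt1, the maintenance methyltransferase gene, which is also tied to DNA replication, fell from 61.2 ± 5.41 in HFD_WT to 24.4 ± 1.16 CPM in HFD_TKO, and its partner Uhrf1 fell by 1.39 (adjusted p = 9.8e-05). In the same libraries all 18 cell cycle genes were lower.

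Clock genes were lower on HFD in WT, 9 of 16 lower and 4 higher, the same adjusted over the list alone (median -0.83, camera adjusted p = 0.0059; adjusted p = 0.33 with an estimated correlation), with Nr1d1 down from 269 ± 47.5 to 78.1 ± 3.79 CPM and Dbp from 158 ± 16.0 to 53.0 ± 6.39 CPM. In TKO 5 were lower and 1 higher on HFD (7 and 2 adjusted over the list alone; -0.27, camera adjusted p = 0.0034; adjusted p = 0.38 with an estimated correlation). For the interaction 7 were higher and 3 lower (8 and 4 adjusted over the list alone; 0.42, camera adjusted p = 0.051; adjusted p = 0.52 with an estimated correlation), and the list was called without ND_WT replicate 3 (adjusted p = 0.038), ND_TKO replicates 2 (0.046) or 3 (0.047), HFD_WT replicate 2 (0.039) or HFD_TKO replicate 1 (0.019). On ND 4 were lower in TKO (8, with 1 higher, adjusted over the list alone; camera adjusted p = 0.077, and 0.035 with TMM-scaled CPM; adjusted p = 0.83 with that scaling and an estimated correlation), and Bhlhe41 fell from 53.0 ± 8.75 to 24.0 ± 2.27 CPM. The time of day of collection was not given in the sources used here. Immediate early and heat shock genes, which respond to handling, were higher on HFD in 12 of 17 in WT, the same adjusted over the list alone (1.35, camera adjusted p = 0.011; adjusted p = 0.65 with an estimated correlation). In TKO 4 were higher, the same adjusted over the list alone (0.86, camera adjusted p = 0.015; adjusted p = 0.69 with an estimated correlation), a list call that ended without ND_TKO replicate 1 (adjusted p = 0.10) or HFD_TKO replicate 3 (0.066). None of 11 mesothelial genes passed on HFD in TKO (-0.70, camera adjusted p = 0.0034; adjusted p = 0.57 with an estimated correlation), and that list call ended without HFD_TKO replicate 1 (adjusted p = 0.16).

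Besides the matrix list, camera called 7 lists in TKO on ND: fatty acid oxidation (median 0.09, adjusted p = 0.026), histone deacetylases and corepressors (-0.16, 0.026), interferon response (-0.41, 0.026), red blood cells (0.53, 0.030), macrophages (-0.26, 0.042), granulocytes and mast cells (-0.45, 0.042), and endothelial and mural cells (0.09, 0.042). Called members numbered 1 of 21, 2 of 18, 0 of 19, 0 of 6, 1 of 20, 1 of 10 and 2 of 18, or 1, 2, 0, 0, 1, 4 and 5 adjusted over the list alone, all in the direction of their list but 1 of the 5. Adjusted p with an estimated correlation lay between 0.91 and 0.92. Without ND_WT replicate 3 all of these but the deacetylase list (0.025) lost the call (0.64, 0.063, 0.25, 0.22, 0.095 and 0.23 in the order given). Called members were then 2 higher and 1 lower for fatty acid oxidation, 3 lower for macrophages, 3 lower for granulocytes, and 2 higher and 2 lower for endothelial cells. With TMM-scaled CPM the endothelial list had 4 higher and 0 lower, and the deacetylase list 1 lower. With TMM-scaled CPM camera also called the lists of oxidative phosphorylation (0.044) and mesothelium (0.031) on ND, with an adjusted p of 0.87 and 0.83 with an estimated correlation. Oxidative phosphorylation was also called without ND_WT replicate 2 (0.0028) or ND_TKO replicates 1 (0.026) or 2 (0.0082), immediate early genes without ND_WT replicate 1 (0.020) or ND_TKO replicates 1 (0.012) or 3 (0.040), and mesothelium without ND_TKO replicate 3 (0.040). Without ND_TKO replicate 3 the calls of fatty acid oxidation (0.13), interferon response (0.054), red blood cells (0.23), macrophages (0.34) and granulocytes (0.11) ended. Macrophages (0.18), granulocytes (0.097) and endothelial cells (0.081) lost the call without ND_WT replicate 2, red blood cells without ND_WT replicate 1 (0.060), and endothelial cells without ND_TKO replicates 1 (0.052) or 2 (0.16). In TKO on HFD the deacetylase list was not called (6 of 18 lower, 5 adjusted over the list alone, 3 lower and 2 higher with TMM-scaled CPM; camera adjusted p = 0.57). The red blood cell list was not called there either (0.066), but was without HFD_WT replicate 3 (0.022) or HFD_TKO replicate 2 (0.016).

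Lists that camera with the preset correlation called in no comparison, on CPM with all 12 libraries, were those of thermogenic genes, adipose expansion, stromal and adipocyte progenitors, epididymal epithelium (2 of 14 genes tested), skeletal muscle (6 of 12 tested) and the unfolded protein response. With TMM-scaled CPM camera called the thermogenic list for HFD in TKO (adjusted p = 0.036; adjusted p = 0.35 with an estimated correlation). Fry, which does not compare a list with other genes, called the thermogenic list in TKO on HFD (5.1e-04), for HFD in WT (1.2e-04) and for HFD in TKO (0.0054). It also called the stromal list in TKO on HFD (0.0089) and for HFD in WT (0.0024), the skeletal muscle list in TKO on HFD (0.011) and the unfolded protein response for HFD in WT (0.0068). Without single libraries the adipose expansion list was called in TKO on ND (ND_WT replicate 3 left out, adjusted p = 0.0020), and the lists of thermogenic genes (HFD_TKO replicate 3, 0.032) and of the unfolded protein response (HFD_TKO replicate 2, 0.045) for HFD in TKO. Of 9 B and plasma cell genes 6 were higher on HFD in WT (8 adjusted over the list alone; camera adjusted p = 0.094), and that list was called with TMM-scaled CPM (adjusted p = 0.031; adjusted p = 0.57 with an estimated correlation) and without ND_WT replicate 2 (0.023) or HFD_WT replicate 2 (0.0040). For HFD in TKO it was called without ND_TKO replicate 2 (0.025), and the red blood cell list without HFD_TKO replicate 1 (0.020). Of 18 thermogenic genes 4 were higher and 5 lower in TKO on HFD (5 and 7 adjusted over the list alone; 5 and 4 with TMM-scaled CPM; camera adjusted p = 0.57). Ucp1, the thermogenic uncoupling protein gene, stayed below the filter, at a mean of 0.0312, 0.0313, 0.838 and 0.0933 CPM in ND_WT, ND_TKO, HFD_WT and HFD_TKO.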
